A study of Mus musculus with 12 samples.

How the data were processed

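Binding of HIF1A and ARNT was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in N1E115 cells, a mouse neuroblastoma line that the labels describe as positive for the neuronal nitric oxide synthase NOS1. HIF1A is the oxygen-regulated subunit of the transcription factor HIF-1 and ARNT is its constitutive partner. Per the labels, cells were grown for 3 days at 20% or 4% O2 with 5% CO2. Of the 12 samples, 8 were ChIP samples in 4 groups of 2 (each antibody at each oxygen level) and 4 were inputs, 2 at each oxygen level, numbered 4 and 5. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so tests between samples measure only the spread between these samples, which may be technical. Tests over genes, regions or peaks measure no spread between samples and describe these lists.

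Per the submitters' processing notes, BWA, Picard and MACS2 were used, with the mouse build mm10. Their versions and settings are not given in the sources used here. Peaks were called by the authors for each ChIP sample separately, per the sample names in the files: the HIF1A replicate 2 samples against input 5, and the HIF1A replicate 1 samples and all ARNT samples against input 4 of the same oxygen level. HIF1A and ARNT lists called against one input share its chance values, which could not be simulated without reads. Each deposited list gives a position, a name and a score per peak. The score is the authors' own value from the peak caller. Its lowest value lay between 2.00 and 2.19 in the 8 lists and no header names its scale, so the score was used only to rank, filter or describe peaks within a list. A percentile rank is the percent position of a score within its own list, with 100 for the highest.

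The lists came in 2 forms. Both HIF1A replicate 2 lists hold positions of 1 bp, which are read here as summits, and per the labels' design text their reads came from a pair of combined sequencing runs. The other 6 lists hold intervals, with median widths of 129 to 182 bp. Per the file headers, all 4 replicate 1 samples were read on the same lane of a single flow cell, ARNT at 20% O2 replicate 2 on another lane of that flow cell, and ARNT at 4% O2 replicate 2 on another flow cell. The HIF1A replicate 2 lists carry no such header. The lists hold no read counts, so sequencing depth is unknown and no interval of a peak's own value can be given. The number of peaks called rises with depth and with enrichment alike.

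Overlaps needed at least 1 bp. A reproducible region was a merged stretch with a peak in both lists of a group. Shares carry 95% Wilson intervals, which cover counting of regions only. Chance overlap came from 100 random placements on the same chromosome (bedtools 2.31.1). Chromosome lengths were taken as the last annotated or called position. Genes came from an annotation of GRCm38.p6, the same build as mm10. That table has no strand, so a transcription start could not be told from a gene's other end. The distance fixed beforehand, 5 kb from a transcription start (1 kb for location), was therefore measured from either end of a gene. Of 21631 protein-coding genes on chromosomes 1 to 19 and X, those with a reproducible region within 5 kb of an end were counted. Exon and intron positions were not used here.

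The number of peaks and the share near gene ends were compared between oxygen levels with a two-sided exact permutation test that exchanged labels within each antibody (36 arrangements). The share of regions bound by both antibodies was compared with Fisher's exact test over regions, which are not replicates. A set of 14 gene lists was tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 56 tests and a threshold of 0.05. An adjusted exact p is such a value. Log2 odds have 0.5 added to each cell, so a list with no member can lie above 0. Of 327 list entries 326 matched a gene, 6 of them by an alias. Scores of shared and unshared peaks were compared by a permutation test of medians with 100000 resamples, whose smallest p is 1e-05, adjusted over 8 lists. The lists were glycolysis, oxygen sensing, mitophagy and mitochondria, angiogenesis with pH and iron, JmjC demethylases, collagen and matrix, AHR targets, circadian clock, nitric oxide signalling, immediate early genes, sympathoadrenal genes, oxidative phosphorylation, ribosomal proteins, and genes of other tissues as a control.

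Genes were named by a rule fixed before the data were examined, as were the groups, tests, gene lists and most alternatives. The rule took up to 8 members of a list in order of mean percentile rank over both lists of a group. It also took the 10 highest regions at 4% O2, the 10 highest found at 1 oxygen level only, and Hif1a, Arnt, Nos1, Vegfa, Egln3, Bnip3, Pgk1 and Ldha in all cases. Some genes that the rule takes are not reported here. Alternatives were an overlap of 50% of the shorter peak, scores of at least 11.4 (the median of all lists pooled), the 1808 highest peaks of every list (the length of the shortest list), chromosomes 1 to 19 and X, other gene distances and backgrounds, shared against separate inputs, a replicate block, and each replicate left out. Windows of 100 bp on either side of each summit or peak centre, merging of peaks within 1 kb, and whole gene spans with 5 kb were added after seeing the data. Comparisons between the antibodies with a replicate left out, or by input, used such windows. For shares without a peak at the other oxygen level with a replicate left out, only HIF1A replicate 2 used them. The other single lists kept their intervals there. The share of peaks with the HIF core motif needs genome sequence and was not analysed here.

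Overlap and list tests were tested on simulated data first. With 60% of the shorter list planted in the longer, 60.0 to 60.1% was recovered at the 4 pairs of list lengths. The shorter list held 1 bp positions set inside intervals of the longer, a form that only HIF1A at 4% O2 has. Recovery was set by this construction, so it checks the computation and not the other forms of list. All 20 simulated gene lists with 80% of members bound were called and 0 of 20 at the background share of 24%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.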

Results

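HIF1A and ARNT peaks were mapped in N1E115 mouse neuroblastoma cells kept at 20% or 4% O2, with 2 peak lists for each antibody and oxygen level. The comparisons ask where the 2 subunits of HIF-1 bind at each oxygen level and which genes lie there. HIF1A lists held 5393 and 13386 peaks at 20% O2 and 42701 and 13655 at 4% O2, for replicates 1 and 2. Entries of the HIF1A replicate 2 lists are 1 bp summits, counted here as peaks, and several may belong to 1 peak. ARNT lists held 7252 and 1808 peaks at 20% O2 and 24942 and 9920 at 4% O2.

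ARNT peaks were 4.34 times as many at 4% as at 20% O2 (geometric mean of 2 pairs), a log2 ratio of 2.12 ± 0.48 (SD of the replicate ratios, n = 2). HIF1A peaks were 2.84 times as many, a log2 ratio of 1.51 ± 2.09 (SD, n = 2), which is less than the spread between replicates. The HIF1A ratio was 7.92 for replicate 1 and 1.02 for replicate 2. The ARNT ratio was 3.44 for replicate 1 and 5.49 for replicate 2. Over both antibodies the mean log2 ratio was 1.81 (two-sided exact permutation test, p = 0.0556, the smallest that 36 arrangements allow). The exact test of one antibody alone cannot go below p = 0.333. All replicate 1 samples shared a lane, so their ratios of 7.92 and 3.44 are the values within that batch, and the other samples make no batch with both oxygen levels of an antibody by their headers.

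**Figure D1:**
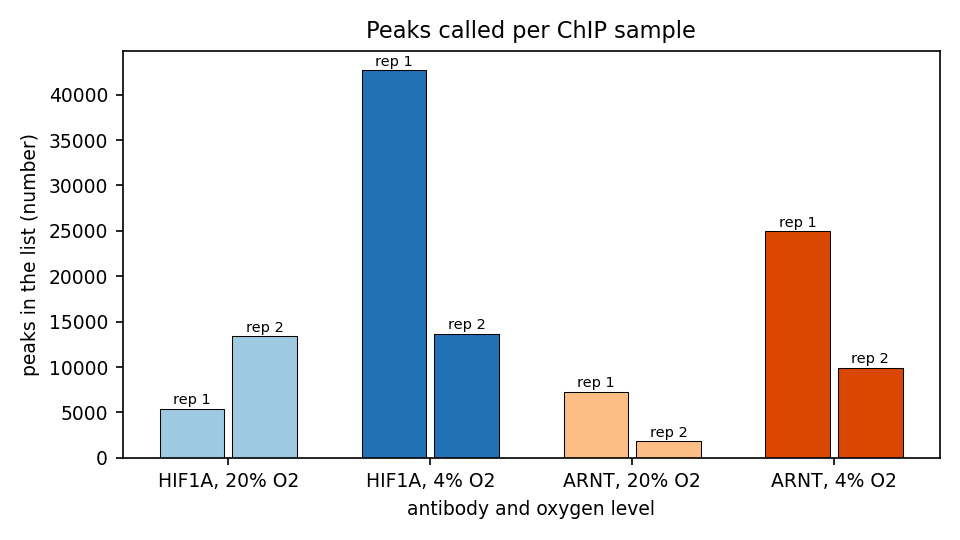
Number of peaks in each of the 8 lists (y axis) by antibody and oxygen level (x axis), 1 bar per replicate. ARNT lists at 4% O2 (24942 and 9920 peaks) both exceed the ARNT lists at 20% O2 (7252 and 1808), while the HIF1A replicate 2 lists differ little (13655 and 13386).

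Most sites of the shorter list of each group recurred in the longer list, and most sites of the longer list did not recur. Of the shorter list, 96.0% of HIF1A peaks at 4% O2 (95% interval 95.6 to 96.3) and 79.3% at 20% O2 (78.2 to 80.3) overlapped the other replicate. The shares for ARNT were 69.9% at 4% O2 (69.0 to 70.8) and 92.3% at 20% O2 (91.0 to 93.5). Of the longer list, the shares were 29.5% and 32.3% for HIF1A and 29.2% and 22.8% for ARNT, at 4% and 20% O2. Random placement gave means of 0.101% to 0.434%. With the 1808 highest peaks of each list, the shares at 20% O2 were 51.2% for HIF1A and 53.3% for ARNT. Regions with a peak in both replicates numbered 12586 for HIF1A and 6893 for ARNT at 4% O2, and 4275 and 1647 at 20% O2. From the 1808 highest peaks of each list they numbered 1457 and 1117 at 4% O2, and 926 and 962 at 20% O2. In all 8 lists the median score, the authors' own value, was higher in peaks shared with the other replicate than in the rest (permutation test of medians, adjusted p = 1e-05 in each, the smallest possible). In HIF1A at 4% O2 replicate 1 these medians were 32.8 for 12586 shared and 10.3 for 30115 unshared peaks. In ARNT at 20% O2 replicate 2 they were 10.4 for 1669 and 6.32 for 139 peaks. Peaks are not replicates, so the p of this test describes these lists only.

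The 3 highest regions at 4% O2 lay at the glycolysis genes Pgam1, Pfkl and Pgk1 in both antibodies. For HIF1A the top region was at Pgam1, a phosphoglycerate mutase (mm10 chromosome 19, 41910447 to 41912064), 615 bp from the nearer gene end by its centre. Next came Pfkl, the liver-type phosphofructokinase (chromosome 10, 78008177 to 78010628), and Pgk1, phosphoglycerate kinase (chromosome X, 106185360 to 106188749). They were followed by P4ha1, a collagen prolyl hydroxylase subunit, Slc16a3, a lactate transporter, and Alkbh5, an RNA demethylase. The rest of the 10 were a site 25380 bp from Psma6, then Narf, Mgat3 and a site inside Egln3, an oxygen-sensing prolyl hydroxylase (chromosome 12, 54190621 to 54193656). ARNT had Pgam1, Pfkl, Pgk1, P4ha1, Alkbh5 and Slc16a3 among its 10 highest too. The other ARNT regions were a site 47318 bp from Hk2, a hexokinase gene, and regions at Mif, Epo, which encodes erythropoietin, and Rassf7. All 20 of these regions had mean percentile ranks of 99.9 or more. Of the 10 HIF1A regions, P4ha1, Alkbh5 and the site near Psma6 had a peak in 1 list at 20% O2 and the others in both. Of the 10 ARNT regions only that near Rassf7 had none.

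Most ARNT regions at 4% O2 had no peak at 20% O2, and nearly all regions at 20% O2 had one at 4% O2. For ARNT, 5277 of 6893 regions at 4% O2 (76.6%, 75.5 to 77.5) had a peak in neither list at 20% O2, 1080 in 1 list and 536 in both. For HIF1A, 5705 of 12586 (45.3%, 44.5 to 46.2) had none, 4217 had a peak in 1 list and 2664 in both. Of these 3 classes of HIF1A regions, 42.0%, 61.7% and 28.1% overlapped an ARNT region of 4% O2. Most HIF1A regions with peaks in both lists at 20% O2 thus had no ARNT region. In the other direction 142 of 4275 HIF1A regions at 20% O2 (3.32%, 2.82 to 3.90) and 77 of 1647 ARNT regions (4.68%, 3.76 to 5.80) had no peak at 4% O2. The 2 lists of a group differed in this. HIF1A at 20% O2 replicate 1 had peaks at 22.4% of the HIF1A regions of 4% O2 and replicate 2 at 53.4%. With single lists of one replicate number the share without a peak was 88.3% for replicate 1 and 50.2% for replicate 2. These single lists differ in form, as replicate 1 entered as intervals and replicate 2 as windows. With the 1808 highest peaks of each list, 76.9% of HIF1A and 63.6% of ARNT regions of 20% O2 had no peak at 4% O2. With replicate 2 alone these shares were 48.9% for HIF1A and 69.7% for ARNT, and with replicate 1 alone 5.53% and 20.9%. Only HIF1A replicate 2 entered as windows here.

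**Figure D2:**
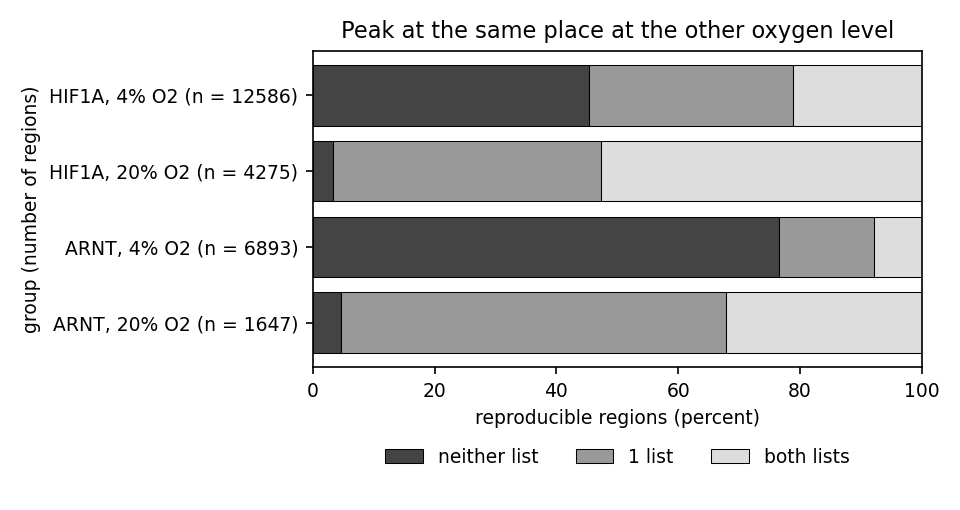
Percent of the reproducible regions of each group (x axis, group and number of regions on the y axis) with a peak in neither, 1 or both lists of the same antibody at the other oxygen level. Regions of 4% O2 without a peak at 20% O2 made up 45.3% for HIF1A and 76.6% for ARNT, against 3.32% and 4.68% in the other direction.

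Among ARNT regions at 4% O2 without any ARNT peak at 20% O2, the highest lay near Rassf7, near Psma6 and at Bnip3, a mitophagy receptor (chromosome 7, 138908749 to 138910371). The next were in Kdm6b, a histone H3 lysine demethylase, in Mrpl45, and at Fam162a and P4ha2, followed by regions near Garre1 and Fbxo16 and in Hilpda, a lipid droplet protein. Their mean percentile ranks were 99.7 to 99.9. The class concerns the region and not the gene. Elsewhere in the gene or the 5 kb around it, ARNT at 20% O2 had 1 and 1 peaks at Kdm6b and 2 and 0 at P4ha2. HIF1A had a reproducible region at 20% O2 at both genes. The 10 highest HIF1A regions of 4% O2 without a HIF1A peak at 20% O2 ranked lower, from 97.7 to 98.6, and lay away from gene ends. They included regions inside Kcnab2, Pebp4, Gphn and Dpp4, and between genes near Syt1, Egfl7, Actl6a, Bdh1 and Tiparp, at 9078 to 67732 bp from the nearest gene end. Which HIF1A regions count here rests mostly on HIF1A at 20% O2 replicate 2, which had a peak at 6722 of the 12586 regions of 4% O2, against 2823 for replicate 1.

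Regions found at 20% O2 and in neither list at 4% O2 were few. For HIF1A the highest 10 lay near Fcgr4 (2 regions), Urb2, Klrb1c, Syn3, 1700028K03Rik, Zfp213, BC035044, H4bc24 and Dhx37, and 5 of them were within 1 kb of a tRNA gene. For ARNT they lay near or in Edem1, Tmx3, Meis2, Etv6, Ccdc7b, Clpb, Anks1, Jagn1, Cfap126 and Dip2b. Mean percentile ranks ran from 85.0 to 96.4 for HIF1A and from 80.3 to 93.8 for ARNT. The highest regions at 20% O2, chosen after their values were seen, lay at Narf for both antibodies, with peaks in both lists at 4% O2. Behind Narf came Mkks, Slmap, Usp31 and Cradd for HIF1A, and Srbd1, Top2a, Evi5l and Khsrp for ARNT.

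Glycolysis genes stood out among the fixed lists at 4% O2. HIF1A had a reproducible region within 5 kb of 24 of 26 of them (92.3%, against 24.4% of other genes, log2 odds 4.93, Fisher's exact test, adjusted exact p = 2.16e-11). ARNT had one at 21 of 26 (80.8% against 20.5%, log2 odds 3.92, adjusted exact p = 2.34e-09), all 21 of them also HIF1A genes. Led by Pgam1, Pfkl, Pgk1 and Slc16a3, the list also had Pkm, Eno1, Pdk1 and Aldoa at ranks of 99.8 or more for both antibodies. Pfkfb3, Pfkfb4 and Slc2a3 had a region for HIF1A only, at ranks of 30.8, 14.5 and 14.2. ARNT had peaks in both lists at 4% O2 in these genes or the 5 kb around them (4 and 3, 1 and 1, and 12 and 4). At 20% O2 each antibody had regions at 7 of 26, and they were the same 7 genes: Eno1, Pgam1, Gapdh, Pfkl, Slc16a3, Pgk1 and Pkm. These calls were also above background (log2 odds 3.21, adjusted exact p = 0.000345 for HIF1A and 3.07, adjusted exact p = 0.000545 for ARNT). No glycolysis gene had a region at 20% O2 only. HIF1A at 20% O2 replicate 2 had a peak in or within 5 kb of every glycolysis gene. At many of them replicate 1 had none, as at Hk2, Ldha and Slc2a1 (0 peaks against 2 in replicate 2). The lower number of HIF1A glycolysis genes at 20% O2 thus rests mostly on replicate 1. For ARNT at 20% O2, replicate 2, the shortest list, had no peak at some genes where replicate 1 had one. Examples are Hk1 (3 peaks against 0), Aldoa and Tpi1 (1 against 0 each). At Hk2, Ldha and Slc2a1 both ARNT lists at 20% O2 had 0. The ARNT number at 20% O2 is thus limited by replicate 2.

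Genes of mitochondrial turnover, of blood supply, pH and iron, and of histone demethylation were above background at 4% O2 as well. Mitophagy and mitochondrial genes with a region were 10 of 14 for HIF1A (log2 odds 2.85, adjusted exact p = 0.00131) and 11 of 14 for ARNT (3.67, adjusted exact p = 8.49e-05). They included Bnip3, Ndufa4l2, Fam162a, Ddit4, a stress-induced inhibitor of mTORC1, Higd1a, Lonp1, Bnip3l and Mxi1, while Ulk1 had a region for ARNT only. Angiogenesis, pH and iron genes were 12 of 19 for HIF1A (2.37, adjusted exact p = 0.00167) and 13 of 19 for ARNT (3.00, adjusted exact p = 8.49e-05), among them Epo, Adm, Tfrc, the transferrin receptor, Ero1a, Nos3, Car12, Pgf and Vegfa. JmjC demethylase genes were 11 of 18 (2.25, adjusted exact p = 0.00380) and 12 of 18 (2.89, adjusted exact p = 0.000244), led by Kdm4b, Kdm3a, Kdm6b and Jmjd6, with Kdm5b, Jarid2 and Phf8 behind them. At 20% O2 none of these 3 lists passed the threshold for either antibody, and no member had a region at 20% O2 only. With HIF1A replicate 2 alone at 20% O2 all 3 passed (adjusted exact p = 0.000409, 0.000447 and 0.000962), while with replicate 1 alone at 4% O2 the angiogenesis, pH and iron call of HIF1A ended (adjusted exact p = 0.0648).

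Oxygen-sensing genes were 9 of 15 for HIF1A at 4% O2 (log2 odds 2.18, adjusted exact p = 0.0111) and 7 of 15 for ARNT, which missed the threshold (1.77, adjusted exact p = 0.0514). ARNT passed with 4 of the 8 alternatives, among them the 1808 highest peaks (adjusted exact p = 0.0413). All 7 were also HIF1A genes: Ankrd37, Egln1, Cited2, Vhl, Hif3a, Siah2 and Cdkn1a. Ankrd37 was the one member with a region at 20% O2, in both antibodies, at ranks of 99.7 and 99.8. Collagen and matrix genes were 6 of 15 for each antibody at 4% O2 (1.08, adjusted exact p = 0.348 for HIF1A and 1.40, adjusted exact p = 0.208 for ARNT). The 6 were P4ha1, P4ha2, Plod2, Plod3, Loxl2 and Plod1, enzymes that hydroxylate or cross-link collagen. With the 1808 highest peaks the list passed at 4% O2 for both antibodies (log2 odds 3.97 for HIF1A and 4.23, adjusted exact p = 4.42e-05 for ARNT). At 20% O2 this list passed for HIF1A with 4 of 15 (3.23, adjusted exact p = 0.00848), namely Loxl1, P4ha2, Plod1 and Plod2. That call ended within 1 kb of gene ends (adjusted exact p = 1), with the 1808 highest peaks (1) and with replicate 2 alone (0.0526).

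Circadian clock genes had regions at 14 of 21 for each antibody at 4% O2, the same 14 genes (log2 odds 2.58, adjusted exact p = 0.000345 for HIF1A and 2.90, adjusted exact p = 8.49e-05 for ARNT). Bhlhe40, a repressor of clock transcription, ranked highest at 99.7 and 99.5, followed in the order of HIF1A ranks by Ciart, Dbp, Nr1d1, Bhlhe41, Cry2, Per1 and Cry1. Immediate early genes were 15 of 21 for HIF1A (2.88, adjusted exact p = 8.49e-05) and 10 of 21 for ARNT (1.82, adjusted exact p = 0.0150), led by Ier3, Btg2, Fosb and Fosl2, then Dusp1, Atf3, Bdnf and Jun. At 20% O2 HIF1A had 6 immediate early genes (3.33, adjusted exact p = 0.000679), namely Dusp1, Jun, Atf3, Btg2, Arc and Fosb, and ARNT had 0 (adjusted exact p = 1). The difference between the antibodies was not tested.

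Sympathoadrenal genes, which mark the lineage of neuroblastoma, were 11 of 18 for HIF1A at 4% O2 (log2 odds 2.25, adjusted exact p = 0.00380) and 5 of 18 for ARNT (0.65, adjusted exact p = 0.568). Ddc and Dbh, enzymes of catecholamine synthesis, ranked highest for HIF1A at 91.3 and 87.0, followed by Chga, Hand1, Mycn, Phox2a, Th and Hand2. Ribosomal protein genes were 22 of 50 for HIF1A (1.29, adjusted exact p = 0.00848) and 18 of 50 for ARNT (1.14, adjusted exact p = 0.0358), among them Rpl5 and Rps29 for both antibodies. Oxidative phosphorylation genes were 14 of 39 and 10 of 39 at 4% O2 (adjusted exact p = 0.249 and 0.587). At 20% O2 HIF1A passed with 6 of 50 ribosomal (1.81, adjusted exact p = 0.0389) and 5 of 39 oxidative phosphorylation genes (1.93, adjusted exact p = 0.0489). AHR targets, 3 of 10 for each antibody at 4% O2 (Tiparp, Nqo1 and Nfe2l2), did not pass (adjusted exact p = 0.830 and 0.587). Genes of other tissues were 4 of 32 and 3 of 32 at 4% O2, below the background but not past the threshold (log2 odds -1.04, adjusted exact p = 0.269 and -1.13, adjusted exact p = 0.249). For HIF1A they passed as lower within 20 kb (adjusted exact p = 0.0270) and with replicate 1 alone (0.00358).

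Against genes with any peak in the 8 lists, the calls at 4% O2 ended for HIF1A in oxygen sensing (log2 odds 1.63, adjusted exact p = 0.293), mitophagy (1.78, 0.190), JmjC (1.02, 0.403), immediate early (1.69, 0.0556), sympathoadrenal (1.02, 0.403) and ribosomal genes (0.07, 1). For ARNT they ended in JmjC (1.81, 0.0536), immediate early (0.63, 0.631) and ribosomal genes (0.00, 1). Genes without any peak drop out there and all genes with a region stay, and the log2 odds stayed above 1 in all of these lists but ribosomal genes and the immediate early genes of ARNT. The HIF1A calls at 20% O2 for oxidative phosphorylation (0.332) and ribosomal genes (0.415) ended too. Other alternatives ended the HIF1A calls at 4% O2 for JmjC genes (within 20 kb, adjusted exact p = 0.112) and sympathoadrenal genes (within 1 kb, 0.234, within 20 kb, 0.0628, and with the 1808 highest peaks, where the log2 odds were -0.70), and the ARNT call for immediate early genes (within 1 kb, 0.0811, and over gene spans, 0.0522). Ribosomal genes kept their call in 4 of 8 alternatives for HIF1A and 2 of 8 for ARNT at 4% O2, and at 20% O2 HIF1A kept it in 3 of 8 for ribosomal and 2 of 8 for oxidative phosphorylation genes. With replicate 2 alone at 20% O2 HIF1A passed for clock (adjusted exact p = 7.54e-05) and sympathoadrenal genes (0.000962). Glycolysis and the clock stayed past the threshold for both antibodies at 4% O2 in all 8 alternatives, with adjusted p up to 0.0457.

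**Figure D3:**
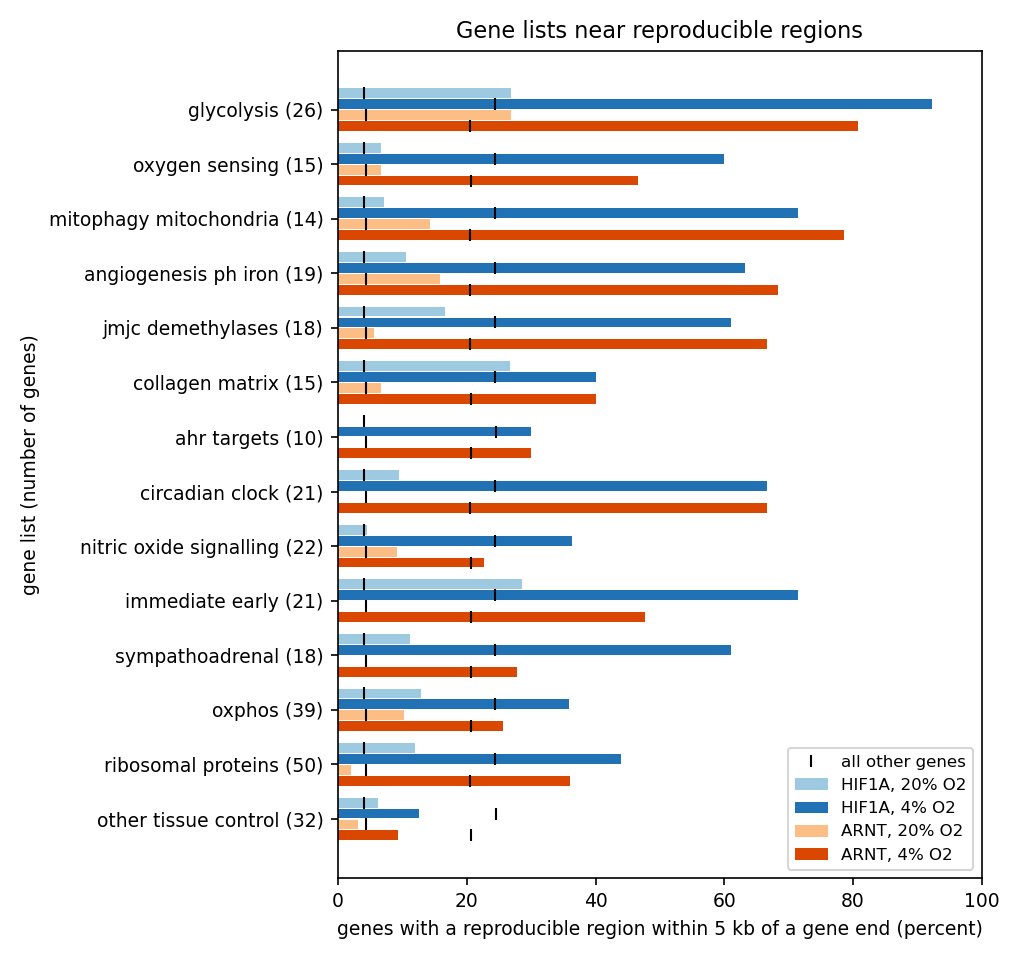
Percent of the genes of each list (y axis, number of genes in brackets) with a reproducible region within 5 kb of a gene end (x axis). Bars give the 4 groups and black ticks the percent of all other protein-coding genes in that group. Glycolysis reached 92.3% for HIF1A and 80.8% for ARNT at 4% O2, against 24.4% and 20.5% of other genes.

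Nos1, the synthase named in the cell line's description (chromosome 5, 117866839 to 117958840), had no peak in any of the 8 lists in or within 5 kb of the gene. Nitric oxide signalling genes had regions at 8 of 22 for HIF1A and 5 of 22 for ARNT at 4% O2 (log2 odds 0.86, adjusted exact p = 0.343 and 0.28, adjusted exact p = 0.888). Dynll1, a dynein light chain that binds NOS1, ranked highest at 97.2 and 97.7, followed by Asl, Dlg4, Gucy1a1, Grin1, Prkg1, Ass1 and Ddah1 for HIF1A. At 20% O2 Prkg1 had a region for both antibodies and Dynll1 for ARNT. With whole gene spans the list passed for HIF1A at 4% O2 (log2 odds 1.74, adjusted exact p = 0.0141).

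Of the genes named in all cases, Pgk1 had a region for both antibodies at both oxygen levels. Bnip3, Ldha, a lactate dehydrogenase subunit, and Vegfa, the angiogenic growth factor, had regions for both antibodies at 4% O2 and none at 20% O2. In these 3 genes and the 5 kb around them HIF1A at 20% O2 replicate 2 had 2 peaks each and replicate 1 had 0. Egln3 had 10 and 5 HIF1A peaks and 10 and 4 ARNT peaks at 4% O2 in the gene and the 5 kb around it, and near a gene end only a HIF1A region, at rank 32.3. Hif1a and Arnt had no reproducible region within 5 kb of an end in any group. Inside Hif1a and its surroundings there were 2 and 1 peaks for each antibody at 4% O2 and 0 at 20% O2. In Arnt and the 5 kb around it each antibody had 1 and 1 peaks at 20% O2, and ARNT had 1 and 0 at 4% O2.

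**Figure D4:**
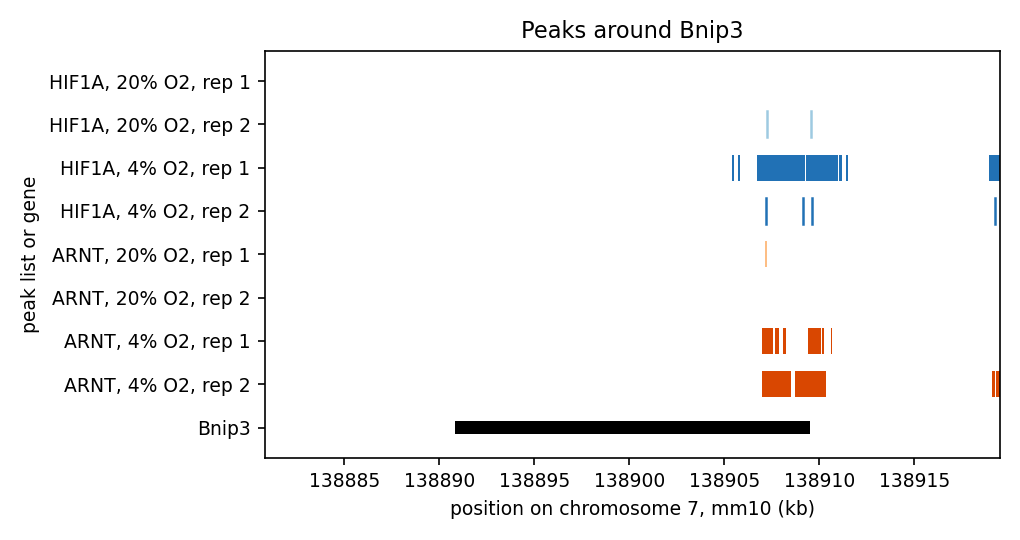
Peaks of the 8 lists (y axis) around Bnip3 on mm10 chromosome 7 (x axis, kb), with the annotated gene in black. Boxes are peak intervals and thin ticks are the 1 bp summits of the HIF1A replicate 2 lists. All 4 lists at 4% O2 have peaks at the right end of the gene, and at 20% O2 HIF1A replicate 2 has 2 and ARNT replicate 1 has 1.

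HIF1A and ARNT shared more of their regions at 4% than at 20% O2. At 4% O2, 5745 of 12586 HIF1A regions (45.6%, 44.8 to 46.5) overlapped an ARNT region, against 904 of 4275 at 20% O2 (21.1%, 19.9 to 22.4), a difference of 24.5 percentage points (Fisher's exact test over regions, p = 3.01e-187). Regions are not replicates, so this p describes these lists. There were fewer ARNT than HIF1A regions, which limits the share to about 54.8% at 4% O2 and 38.5% at 20% O2. Region numbers may thus set part of the difference. For ARNT regions the limit was 100% at both oxygen levels. Of the ARNT regions, 83.7% (82.8 to 84.5) at 4% O2 and 55.2% (52.8 to 57.6) at 20% O2 overlapped a HIF1A region, a difference of 28.5 points (Fisher's exact test, p = 1.19e-123). Random placement gave 0.194% of HIF1A regions at 4% O2 and 0.0339% at 20% O2. With the 1808 highest peaks of each list the shares were 70.3% and 31.9% of HIF1A regions and 91.8% and 30.9% of ARNT regions. Among genes, 3643 had regions of both antibodies at 4% O2, against 1090 from independent lists, and 221 at 20% O2, against 38.2. This expectation treats all 21631 protein-coding genes alike, though 11329 of them had a peak in any of the 8 lists. Part of the excess may thus come from genes that gather peaks in general, which was not tested.

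The direction held at equal list length and turned in some full lists. With replicate 1 alone, the difference in HIF1A peaks turned to -8.39 points, and with HIF1A replicate 1, which shares its input with ARNT, set against the ARNT regions it was -2.68 points, while HIF1A replicate 2 with a separate input gave 33.0 points. For ARNT peaks the difference was -3.80 points with replicate 2 alone, and 9.64 points with HIF1A replicate 2 set against the ARNT regions. By single lists, HIF1A replicate 1, with the same input as ARNT, overlapped 84.4% and 84.9% of the peaks of ARNT replicates 1 and 2 at 4% O2 and 42.5% and 57.1% at 20% O2. HIF1A replicate 2, with another input, overlapped 43.2% and 67.9% at 4% O2 and 61.7% and 71.7% at 20% O2. Among the 1808 highest peaks of each list the shares with the same input were 65.2% and 59.2% at 4% O2 and 32.5% and 36% at 20% O2. With another input they were 67.7% and 72.4% at 4% O2 and 28.4% and 27.9% at 20% O2, so the share was higher at 4% O2 in all 4 pairings.

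Peaks of both antibodies lay at gene ends more often than the genome's share. Centres within 1 kb of a gene end made up 7.77% to 41.3% of the peaks per list, against 2.98% of the genome. The share was lowest for HIF1A at 20% O2 replicate 1 (7.77%) and highest for ARNT at 4% O2 replicate 2 (41.3%). It averaged 28.9% in the 4 lists at 4% O2 and 21.4% in the 4 at 20% O2, a difference of 7.44 points that did not pass (two-sided exact permutation test, p = 0.278). The smallest p of this test is 0.0556, so it cannot pass 0.05, and with the 1808 highest peaks of each list the difference was 10.1 points at that p of the exact test. In full lists the share at gene ends was higher at 4% than at 20% O2 in every same-numbered pair. For HIF1A it was 21.8% against 7.77% in replicate 1 and 27.6% against 22.7% in replicate 2. For ARNT it was 24.7% against 23.0% and 41.3% against 32.2%. By class, 39.7% of ARNT regions at 4% O2 without a peak at 20% O2 lay there, against 56.7% of those with peaks in both lists. For HIF1A at 4% O2 the shares were 29.6% without a peak at 20% O2, 36.5% with a peak in 1 list and 9.23% in both.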

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

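The count of mitochondrial peaks was chosen only after the lists were seen. Peaks on the mitochondrial chromosome lay outside every comparison that uses genes. There were 8 in ARNT at 20% O2 replicate 1 and 5 in ARNT at 4% O2 replicate 1, above the limit of 3 that a count of 0 allows, which is what singled them out. That limit is no test of a difference between lists, which differ in length. ARNT at 4% O2 replicate 2 had 2, and ARNT at 20% O2 replicate 2 and all HIF1A lists had 0. The highest of them lay at 15882 to 16287 in ARNT at 20% O2 replicate 1 and at 15893 to 16278 in ARNT at 4% O2 replicate 1, with percentile ranks of 99.9 and 99.3.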

How the results depend on the processing

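Of the values that answer a comparison, each recomputed under an alternative, 108 stayed the same, 36 moved and 3 reversed. Windows, merged peaks, gene spans and left-out replicates for location were chosen after seeing the data. Where the text gives no cause, the cause was not tested. Of the values for single lists and groups, 356 stayed the same, 36 lost and 23 gained a call, 30 changed sign without a call and 3 reversed.

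Under the stricter score the ARNT log2 ratio of peaks was 2.60, replicate overlap was 97.0% for HIF1A and 63.7% for ARNT at 4% O2 and 88.0% for ARNT at 20% O2, and reproducible regions numbered 7042 and 1734 for HIF1A and 3837 and 645 for ARNT, at 4% and 20% O2. These counts are lower because fewer peaks enter. At equal list length overlap was 80.6% and 51.2% for HIF1A and 63.3% and 53.3% for ARNT, regions numbered 1457, 926, 1117 and 962, and 76.9% of HIF1A and 63.6% of ARNT regions of 20% O2 had no peak at 4% O2. An overlap of 50% gave 67.9% for ARNT at 4% O2. Windows gave 92.5% and 84.9% for HIF1A at 4% and 20% O2.

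With 1 replicate left out, a group's list took the place of its regions, so the numbers ranged from 13655 to 42701 and 5393 to 13386 for HIF1A and from 9920 to 24942 and 1808 to 7252 for ARNT, at 4% and 20% O2. Shares without a peak at the other oxygen level ranged from 50.2% to 88.3% and 5.53% to 48.9% for HIF1A and from 77.0% to 94.6% and 20.9% to 69.7% for ARNT. In these shares HIF1A replicate 2 entered as windows and the other lists as intervals. The difference in co-occupancy ranged from -8.39 to 39.9 points of HIF1A and from -3.80 to 41.9 points of ARNT peaks, and was -2.68 points with the HIF1A list sharing the input of ARNT.

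Called gene lists, 9 and 5 for HIF1A and 7 and 1 for ARNT at 4% and 20% O2, numbered 3 and 3 for HIF1A and 4 for ARNT at 4% O2 against genes with any peak, 3 for HIF1A at 20% O2 at equal list length, and 2 for ARNT at 20% O2 within 20 kb. With a replicate left out they ranged from 4 to 8 for HIF1A and 1 to 4 for ARNT at 20% O2. Log2 odds turned to -0.70 for sympathoadrenal genes in HIF1A at 4% O2 and to -0.39 for ribosomal genes in HIF1A at 20% O2 at equal list length, and ranged from -1.09 to 1.69 for clock genes in ARNT at 20% O2 with a replicate left out.

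With a replicate block the log2 ratio of peaks was 1.81 (exact sign-flip test over 4 pairs, p = 0.125, the smallest possible). The replicate number goes with a lane in replicate 1, and in HIF1A replicate 2 with input 5, summits and combined runs, but with no shared lane in ARNT replicate 2. Deviations of same-numbered lists correlated at 0.234 over HIF1A and 0.0278 over ARNT regions, in 2 lists per group. The motif share was not run. Without read counts, how depth limits the lists is unknown.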

Other observations

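The tests of tRNA genes, of the HIF1A lists at 20% O2, and of glycolysis and ribosomal genes on their own were chosen only after the results were seen. The other 2 tests of gene lists were fixed before.

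Many tRNA genes had a HIF1A peak at 20% O2, though these were 2.74% and 1.42% of the peaks of the 2 lists. Of 408 tRNA genes on chromosomes 1 to 19 and X, 163 (40.0%) had a reproducible HIF1A region within 1 kb at 20% O2 and 47 (11.5%) at 4% O2. ARNT had regions at 3 (0.735%) and 21 (5.15%). Other small RNA genes were rarely marked by HIF1A at 20% O2, with 0.448% of snoRNA, 0.598% of snRNA and 0.407% of miRNA genes. HIF1A regions of 20% O2 without a peak at 4% O2 included 29 of 142 near a tRNA gene. Those with a peak in 1 list at 4% O2 included 94 of 1878, and those with peaks in both lists 16 of 2255. Most HIF1A regions near tRNA genes at 20% O2 thus had a peak at 4% O2. In full lists of HIF1A, 173 tRNA genes had a peak at 4% O2 in replicate 1 (42701 peaks) and 49 in replicate 2 (13655 peaks), against 167 (5393 peaks) and 198 (13386 peaks) at 20% O2. The difference between oxygen levels was not tested.

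Among the 1808 highest peaks of each list, 109 and 101 tRNA genes were marked in the HIF1A lists at 20% O2 and 10 at most in any other. At this equal number of peaks the lower HIF1A list at 20% O2 had 10.1 times the tRNA genes of the highest other list. Strong sites at 4% O2 can push tRNA peaks out of such a cut, so it cannot decide for those lists. List length as the whole cause was argued against by full HIF1A lists of like length. Replicate 2 had 198 tRNA genes at 20% O2 (13386 peaks) and 49 at 4% O2 (13655 peaks). The longest list, HIF1A at 4% O2 replicate 1, had 173. For replicate 1, a shared input library was argued against by the 7 tRNA genes of ARNT at 20% O2 replicate 1, called against the same input 4. In the test of reads shared between gene copies, all 6 other lists had under 50% of the lower HIF1A list. By the limit above, the lists at 4% O2 do not bear on it. The ARNT lists at 20% O2 argue against shared reads, with 7 and 3 tRNA genes in the cut and 34 and 3 in full. An antibody effect that shows where HIF1A is scarce, or HIF1A itself at these genes, may remain, and neither was tested.

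The 2 HIF1A lists at 20% O2 differed at the strongest sites of 4% O2. Of the 1000 regions that ranked highest over both antibodies at 4% O2, replicate 2 at 20% O2 had a peak at 90.9% (89.0 to 92.5) and replicate 1 at 19.3% (17.0 to 21.9), with 31.1% and 12.1% for ARNT. A longer list was argued against as the whole cause by equal numbers of peaks, at which the share was 5.92 times as high in replicate 2 (52.7% and 8.90%). The form of the lists was argued against by windows of one width, with a ratio of 5.26. Reads of the 4% O2 culture in that library cannot be told apart from weaker binding at the same sites: its scores correlated with those of HIF1A at 4% O2 replicate 2 at a Spearman rho of 0.713 across 909 regions, against 0.858 between the 2 HIF1A lists at 4% O2, which both explanations allow, and regions are not independent replicates.

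Lists above background at 4% O2 may hold genes that are active or open in general, since promoters of such genes gather peaks. The test against genes with any peak keeps every gene with a region and drops only genes without one, so log2 odds can fall by its construction, and a lost call is no evidence for this explanation. For glycolysis the log2 odds were 4.93 before and 4.23 after in spite of this. That argues against having any peak as the whole explanation for that list. Genes with any peak are not matched on activity, so a high activity of glycolysis genes was not tested. For HIF1A, 2 of 5 hypoxia lists (glycolysis, angiogenesis with pH and iron) and 1 of 4 other lists (the clock) stayed past the threshold. For ARNT glycolysis, mitophagy, angiogenesis with pH and iron, and the clock did. The explanation stays open for the other lists, and as to activity for these lists too. Log2 odds went from 2.18 to 1.63 for oxygen sensing, 2.85 to 1.78 for mitophagy, 2.25 to 1.02 for JmjC, 2.88 to 1.69 for immediate early, 2.25 to 1.02 for sympathoadrenal and 1.29 to 0.07 for ribosomal genes.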
